A study of Homo sapiens with 4 samples.

How the data were processed

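Total RNA of the LNCaP and C4-2B prostate cancer lines and of a commercial benign prostate pool was amplified, labelled with Cy3 or Cy5 and hybridised to 2-colour Agilent whole human genome arrays. LNCaP was cultured in RPMI and C4-2B in T-medium, each with 10% fetal bovine serum and without treatment, per the labels. Each line occupied 2 arrays, 1 per dye orientation, and which dye carried the line was taken from the labels. All 4 samples were used. The arrays were 4 slides scanned on 2 days, 1 day per line.

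The spot intensity values are mean pixel brightness per dye with the local background given separately, as the authors' scanner software Agilent Feature Extraction 9.1.3.1 wrote them, per the file headers and the submitters' processing notes. The same files hold a log10 ratio of Cy5 over Cy3 that was background-subtracted, detrended and dye-normalized, per the file headers. The series table deposited by the authors holds log10 ratios equal to those values, with the sign turned on the dye-flipped arrays (largest difference 5e-06) and entries missing where the ratio was 0. Its column medians were 0.0881 and -0.00416 for LNCaP and 0.0082 and 0.0048 for C4-2B in Cy5 and Cy3, so it is line over pool with no further centring.

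Log2 ratios were computed here from the deposited intensity values with limma 3.58.1 in R 4.3.3: normexp background correction with an offset of 50, then loess within each array. Control spots had weight 0 in the loess fit and outlier-flagged spots, 33, 139, 7 and 8 per array, were left out. Spots of a probe were averaged. Saturation flags were set in the line channel at 15 and 9 spots of the arrays with the lines in Cy5 and at 0 of the others, and these spots were kept. Calls and summaries were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

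Probes were named through the RefSeq accession in the files where the RefSeq gene table for GRCh38.p14 held it (23434 of 41000 probes), and otherwise by the file's own name. This gave 26979 named probes of 17599 genes, 6898 of them with more than 1 probe, and each gene was represented by its brightest probe. The table served only for names, gene lengths and gene order, and no coordinates are given because the files name no genome build. Of 1555 further probes of genes called between the lines, 591 had the same call, 956 were not called and 8 had the opposite call. XIST, TSIX and Y-linked genes were left out of all results.

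Ratios of C4-2B over LNCaP were differences of line over pool ratios within each dye orientation. A gene was kept where at least 1 of the RNAs compared was well above background on both of its arrays, and called where it differed at least 2-fold in the same direction in both orientations. The dye-swapped arrays of a line count as 1 sample, so no test was made. The median distance of an orientation from the mean was 0.06 for C4-2B over LNCaP, 0.11 for LNCaP over pool and 0.08 for C4-2B over pool. As a gauge of noise between orientations, the rule was repeated with the sign of 1 orientation turned. A turned call needs a distance of at least 1 from the mean, far above these medians. Counts near 0 were therefore nearly fixed in advance. Where a gene was well above background in 1 RNA and on neither array of the other, a lower bound was computed from the line or pool channels after quantile normalization of mean intensity (Aquantile). The bound sets the bright mean against the higher of the dim probe's signal and the lowest signal well above background, and where it exceeded the fold from ratios to the pool both values are given and neither is called a bound. The number of arrays limits the precision.

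Named genes were the 10 highest and 10 lowest called genes measured in both RNAs, the 5 (between lines) or 3 (against the pool) largest bounds per direction, up to 4 called members of each list with the largest ratios, and 12 genes fixed in advance, not all of which are reported. This rule, the lists, the comparisons and 17 alternatives were fixed before the data were examined. ATF4 and the genes named in the closing section outside the rule were chosen after their values were seen. The 29 lists covered markers of luminal and basal epithelium, smooth muscle, fibroblasts and matrix, endothelium, leukocytes, neuroendocrine cells, and nerve and glia. They also covered androgen-induced and androgen-repressed genes, steroid, cholesterol and fatty acid synthesis, cell cycle, interferon-stimulated genes, class I antigen presentation, bone-related genes, epithelial to mesenchymal genes, cancer-testis antigens, metallothioneins and zinc transport, glutathione and detoxification, hypoxia and glycolysis, the unfolded protein and amino acid response, immediate early genes, p53 targets, the insulin-like growth factor axis, thyroid hormone and iron genes, ribosomal proteins and oxidative phosphorylation. A list's median was placed among 10000 random lists of the same size matched on mean intensity in 20 bins, which describes these arrays and is no test.

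The calling steps were tested on simulated arrays of 41000 probes with 200 changed in C4-2B against LNCaP. Of 50 probes changed at each size, 0 were called at 1.5-fold, 43 at 2.5-fold, 50 at 4-fold and 48 at 8-fold, with 0 calls among unchanged probes. The changed probes were drawn from the bright ones, so recovery at dim probes was not tested. The search for shifted neighbouring genes recovered 5 of 5 lowered blocks among 13405 genes with simulated values. These blocks had the length of the searched runs and a cutoff of their own, so recovery of shorter or weaker runs was not tested. The alternatives changed the background correction, offset, normalization, filters, choice of probe, fold threshold and dye orientation, left out each array in turn, and used the deposited log ratios or the line channels alone. After the data were seen, 2 alternatives were added, removal of the trend with gene length and leaving out genes at least 16-fold lower than the pool in both lines.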

Results

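Expression was measured in 2 human prostate cancer cell lines on 4 Agilent whole-genome arrays. LNCaP is an androgen-sensitive line derived from a lymph node metastasis, and C4-2B is a descendant of LNCaP that grows without androgen. Each line was hybridised against the same kind of reference, a commercial pool of RNA from benign prostate tissue, on 2 arrays, 1 with the line in each dye. Each array held 41000 distinct probes. The line's RNA read well above background at 77.7% and 66.8% of spots on the LNCaP arrays with the line in Cy5 and in Cy3, and at 64.4% and 65.7% on the C4-2B arrays. The pool read well above background at 66.5%, 83.8%, 72.3% and 80.7% on the same arrays in that order. Each line counted as 1 sample, so no difference has a replicate check and no p-value is given. The error after each log2 value is the distance of either dye orientation from their mean. A gene was called higher or lower where it differed at least 2-fold in the same direction in both orientations.

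The comparison of C4-2B with LNCaP asked what separates the androgen-insensitive derivative from its parent. Many genes of the unfolded protein and amino acid response and of metallothionein and zinc transport were higher in C4-2B, as were some genes of cholesterol synthesis. BCHE, which encodes butyrylcholinesterase, had a log2 ratio of -6.59 ± 0.17, and genes of the UGT2B family, whose enzymes conjugate androgens, were lower by up to -3.13 ± 0.19 (UGT2B11). The transcription factor gene ASCL2 was 34.8-fold higher, at 5.12 ± 0.04 on its brightest probe, and the intermediate filament gene VIM was higher at 4.05 ± 0.02. A further ASCL2 probe, too dim in both lines to be compared, read 0.10.

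Of 13480 genes compared, 918 were higher in C4-2B and 1620 were lower. With the sign of 1 orientation turned, the same rule called 0 higher and 1 lower. Here and below, such a count is near 0 wherever the orientations agree. It cannot show noise between cultures, RNA samples or scan days. Differences of at least 4-fold were seen for 165 higher and 321 lower genes, and the orientations correlated at r = 0.954 across genes, which are not independent replicates. With the LNCaP array carrying the line in Cy3 left out, and the mean ratio required to reach 2-fold, 1489 genes were higher, against 1100 by that mean rule with all arrays. The arrays of each line were scanned on a day of their own and the lines grew in different media, so the design cannot tell line, day and medium apart. In the pool channel of these arrays the genes called higher and lower had median shifts of 0.06 and -0.08, against 1.53 and -1.60 in the line channel. These values argue against a day effect that reached the pool as the cause of most calls. A day effect on the line RNA alone stays open. The called-lower genes were longer than others, with a median genomic length of 44.4 kb against 26.3 kb for uncalled and 20.2 kb for called-higher genes.

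Among genes measured in both lines, the largest ratios after ASCL2 belonged to GRIN2C (4.70 ± 0.22), the protease inhibitor gene CSTA (4.62 ± 0.01) and IGFBP3 (4.37 ± 0.07), which encodes a binding protein for insulin-like growth factors. SLC7A5, the gene of a large neutral amino acid transporter, followed at 4.12 ± 0.24, then THBS1 at 4.08 ± 0.38. SLC16A3, a lactate transporter gene, was higher at 4.01 ± 0.05, although a further probe of it read -0.45. ACOX2 and CDR1 were higher at 3.99 ± 0.08 and 3.78 ± 0.34, with a further CDR1 probe at 0.95. LAMP3, GALC, PREX1, the branched-chain amino acid transaminase gene BCAT1 and RND3 were higher in C4-2B and well above background on neither LNCaP array. They differed 63.8-fold, 31.7-fold, 13.9-fold, 13.3-fold and 12.9-fold by ratios to the pool. Against the background floor of the line channels alone the values were 90.3-fold, 42.5-fold, 20.4-fold, 17.8-fold and 16.5-fold. Since these exceeded the ratios, no lower bound is given for these genes. A further GALC probe, too dim in both lines to be compared, read 0.04.

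The nuclear long non-coding RNAs MALAT1 and NEAT1 were lower in C4-2B, at -4.78 ± 0.05 and -3.76 ± 0.05. KLHL1 (-4.08 ± 0.24), PHIP (-3.91 ± 0.05), TXNIP (-3.75 ± 0.63) and KTN1 (-3.67 ± 0.01) were also among the 10 lowest measured genes, with ATP1B1 (-3.56 ± 0.00), ZSCAN18 (-3.52 ± 0.14) and the centromere protein gene CENPF (-3.44 ± 0.04). Further probes of PHIP read -2.13 and -0.48, and those of ZSCAN18 -1.21 and -0.46. Below background in C4-2B was SLC22A3, an organic cation transporter gene, which was at least 62-fold lower by the line channels on its brightest probe, while a further probe read -1.94. RIPOR2, CBLN2, DNAJC15 and the ETS factor gene ETV1 were also lower and below background in C4-2B. They differed 39.9-fold, 15.3-fold, 20.7-fold and 6.22-fold by ratios to the pool, and 59.7-fold, 36.9-fold, 32.6-fold and 25-fold by the line channels, so no lower bound is given for them.

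**Figure D1:**
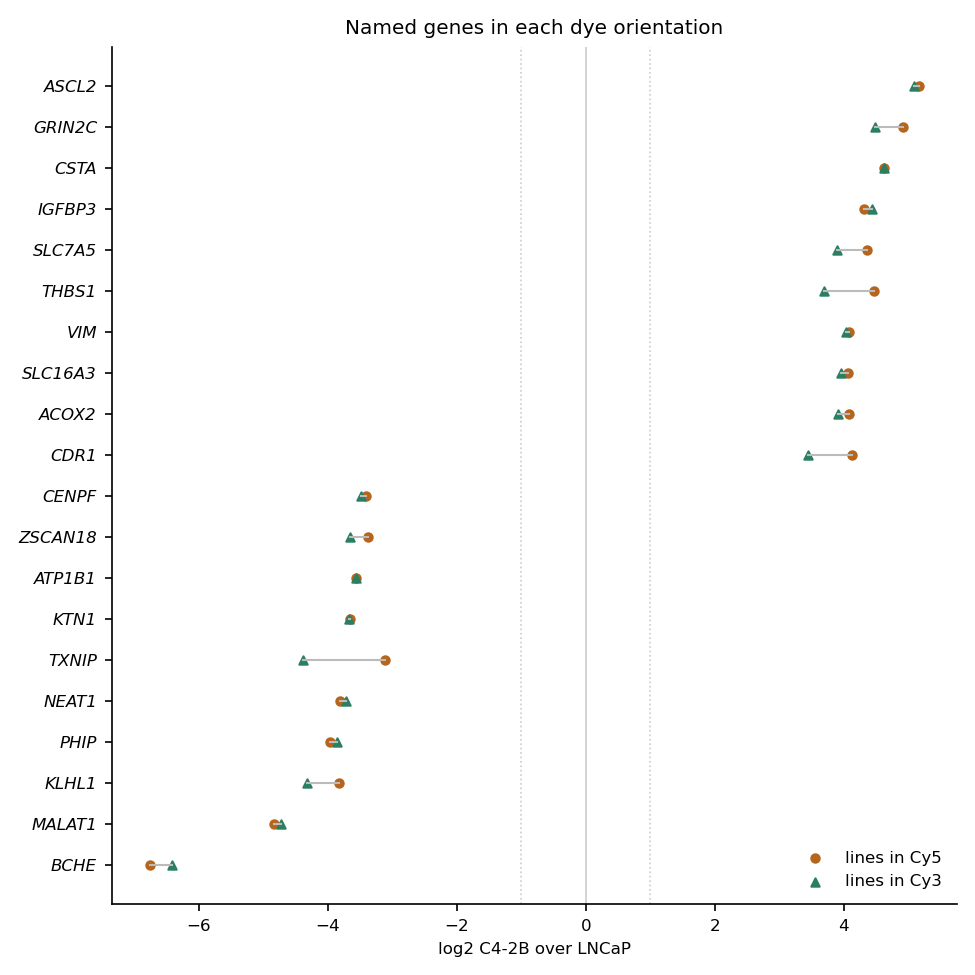
Log2 ratio of C4-2B over LNCaP (horizontal axis) for the 10 highest and 10 lowest genes measured in both lines. Circles show the arrays with the lines in Cy5 and triangles those with the lines in Cy3, dotted lines mark 2-fold, and ASCL2 lies at 5.16 and 5.09 in the separate orientations.

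The genes of the unfolded protein and amino acid response, which adapt cells to misfolded protein and amino acid shortage, had 10 of 17 measured members higher in C4-2B, 0 lower and 7 not called. The transcription factor genes DDIT3 and ATF4 were higher at 2.80 ± 0.42 and 2.02, the chaperone gene HSPA5 at 2.37 ± 0.17 and TRIB3 at 2.64 ± 0.47. Asparagine synthetase, ASNS, was higher at 2.74 ± 0.26 on its brightest probe, while a further probe read -0.71. The list's median of 1.20 stood at percentile 100 among 10000 random lists matched on intensity. Immediate early genes had 1 of 17 higher, 2 lower and 14 not called, and the 1 higher gene was the stress-induced factor ATF3 (2.38 ± 0.05). IER3 and KLF4 were lower at -1.23 ± 0.05 and -1.11 ± 0.05.

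Metallothionein and zinc transport genes, which bind and move zinc, had 11 of 18 members higher, 0 lower and 7 not called, with a median of 1.47 at percentile 100. MT1F and MT2A were higher at 2.17 ± 0.05 and 2.11 ± 0.09, MT1X at 1.69 ± 0.09 and the zinc exporter gene SLC30A1 at 1.77 ± 0.03. The metallothionein genes are close paralogs, and sharing of signal between their probes was not tested. Cholesterol synthesis genes had 9 of 23 higher, 0 lower and 14 not called, with a median of 0.68 at percentile 99.99. INSIG1, a sterol-sensing regulator, was higher at 2.02 ± 0.10, LSS at 1.48 ± 0.00 and MSMO1 at 1.44 ± 0.03. Fatty acid synthesis genes had 3 higher, 1 lower and 12 not called, with the desaturase genes SCD (1.61 ± 0.04) and FADS2 (1.47 ± 0.17) higher and the elongase gene ELOVL6 lower (-2.54 ± 0.12).

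Androgen-repressed genes had 8 of 12 members lower in C4-2B, 0 higher and 4 not called, with a median of -1.94 at percentile 0. In the pool channel 2 of the 12 were also called between the arrays of the lines, against 36 of all 13480 genes. Besides BCHE and UGT2B11, UGT2B15 was lower at -2.90 ± 0.43 and CAMK2N1 at -2.72 ± 0.02. The UGT2B genes are close paralogs too, and sharing of signal was not tested. The members UGT2B10, UGT2B11, UGT2B15, UGT2B17 and UGT2B28 also lie in 1 run of 25 neighbouring genes on chromosome 4. That run had a median of -1.35, with 14 genes lower and 1 higher. The random lists ignored gene order, so for these members a shift of the list cannot be told apart from that of the run. BCHE and CAMK2N1 lie outside it. Androgen-induced genes went both ways, with 5 of 28 higher, 6 lower and 17 not called. MPHOSPH9 (-1.85 ± 0.07) and SLC45A3 (-1.84 ± 0.05) were lower and GNMT was higher (1.75 ± 0.06). HPGD, below background in C4-2B, was lower, 5.54-fold by ratios to the pool and 8.61-fold by the line channels, and a further HPGD probe read -0.87. TMPRSS2 read -0.93 ± 0.13 and KLK2 0.10 ± 0.29. KLK3, which encodes prostate-specific antigen, read -0.50 ± 0.26 on its brightest probe, and its other probes read -1.21 and 0.95. FOLH1, the gene of prostate-specific membrane antigen, was lower at -1.27 ± 0.09, with a further probe at -0.41. None of 13 measured steroid synthesis and breakdown genes was called.

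Cell cycle genes had 7 of 34 members lower, 0 higher and 27 not called, with a median of -0.66 at percentile 0. Besides CENPF, the mitotic kinase gene TTK was lower at -2.12 ± 0.50, NDC80 at -1.95 ± 0.09 and BUB1B at -1.93 ± 0.29. The p53 target genes had 4 of 15 lower, 0 higher and 11 not called, led by RRM2B (-1.57 ± 0.05), BBC3 (-1.51 ± 0.30) and BTG2 (-1.40 ± 0.02), with the other BBC3 probes at 0.27 and 0.63.

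Genes of the epithelial to mesenchymal list had 4 of 16 higher, 1 lower and 11 not called. FN1, the fibronectin gene, was higher at 2.59 ± 0.02 and SNAI2 at 1.69 ± 0.11, with VIM as above, while TWIST1 was lower at -2.77 ± 0.38. The insulin-like growth factor axis had 3 of 15 higher, 1 lower and 11 not called, with IRS1 (1.51 ± 0.28) and IGF1 (1.38 ± 0.19) higher beside IGFBP3 and the receptor gene IGF2R lower (-1.28 ± 0.07). Its median of 0.52 stood at percentile 99.0. Bone-related genes had 1 of 10 higher, 2 lower and 7 not called. BMP7, a bone morphogenetic protein gene, was higher at 3.50 ± 0.16, BMP6 was lower at -1.68 ± 0.06 and CTSK at -1.59 ± 0.04, while SPP1 was near background in both lines. Cancer-testis antigens had 5 of 16 higher, 0 lower and 11 not called. MAGEA1 was higher at 3.56 ± 0.71, PAGE1 at 3.26 ± 0.31, MAGEA8 was higher, 5.21-fold by ratios and 7.93-fold by the line channels, and SAGE1 at least 3.09-fold. By the deposited log ratios PAGE1 read -0.12.

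Interferon-stimulated genes had 2 of 23 higher, 5 lower and 16 not called. IFIT2 (-2.14 ± 0.20), IFIT1 (-2.08 ± 0.19) and IFI44 (-2.01 ± 0.11) were lower and the factor gene IRF7 was higher (1.45 ± 0.04). Class I antigen presentation genes had 2 of 15 lower, HLA-F (-1.31 ± 0.06) and TAP1 (-1.28 ± 0.10), 0 higher and 13 not called. Thyroid hormone and iron genes had 2 higher, 2 lower and 10 not called. The ferritin genes FTH1 and FTL were higher at 1.39 ± 0.12 and 1.22 ± 0.08, and the transferrin receptor gene TFRC was lower at -1.63 ± 0.04, as was KLF9 at -2.12 ± 0.10. Glutathione and detoxification genes had 1 of 21 higher, the heme oxygenase gene HMOX1 (2.05 ± 0.08), 2 lower, GSTA4 (-1.78 ± 0.04) and PRDX1 (-1.07 ± 0.03), and 18 not called. Hypoxia and glycolysis genes had 1 of 21 higher, VEGFA (1.84 ± 0.10), 1 lower, EGLN3 (-1.15 ± 0.11), and 19 not called. Oxidative phosphorylation genes had 3 of 28 lower, UQCRB (-1.91 ± 0.04), COX6C (-1.90 ± 0.04) and NDUFB3 (-1.59 ± 0.04), 0 higher and 25 not called. Ribosomal protein genes had 1 of 30 higher and 0 lower.

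Luminal markers had 4 of 18 higher, 3 lower and 11 not called. The peptidase gene DPP4 was higher, 8.66-fold by ratios and 9.34-fold by the line channels, and AZGP1 was higher at 2.07 ± 0.01. The keratin gene KRT8 was higher at 1.09 ± 0.02, while KRT18 read 0.52 ± 0.05. Markers of other prostate cell types were mostly not called between the lines. Basal markers had 1 of 17 called, CSTA, with KRT5 at 0.23 ± 0.17, and smooth muscle markers had 1 of 16, CALD1, lower at -1.37 ± 0.06. Fibroblast and matrix markers had 1 of 19, VIM, leukocyte markers 1 of 15, CD68 at 1.70 ± 0.16, and nerve and glia markers 1 of 3, PMP22 at 1.40 ± 0.28. None of 8 endothelial markers was called. Of 7 measured neuroendocrine markers, CALCA was higher (3.24 ± 0.00, above background on 1 of 2 LNCaP arrays), ENO2 and CPE were lower (-2.15 ± 0.01 and -1.23 ± 0.04), and 4 were not called.

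Further probes of several named genes were not called between the lines. They read -0.69 for CAMK2N1, -0.51 for IFIT2, -0.53 for HLA-F, -0.36 and -0.23 for CALD1, -1.09 for NDC80 and -0.91 for IGF2R. They read 0.55 for VEGFA, 0.64 for SNAI2, 0.73 for MSMO1, 1.01 for LSS, 0.87 and 0.66 for FTH1, 1.08 for IGF1, 1.04 for KRT8 and -0.65 for KLK2. Further probes with the same call but a smaller ratio read 2.47 for CSTA, 1.51 for SLC7A5, 1.74 for BMP7, -1.82 and -1.43 for MALAT1, -1.53 for NEAT1 and -2.22 for CENPF. All other values and bounds are those of a gene's brightest probe.

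**Figure D2:**
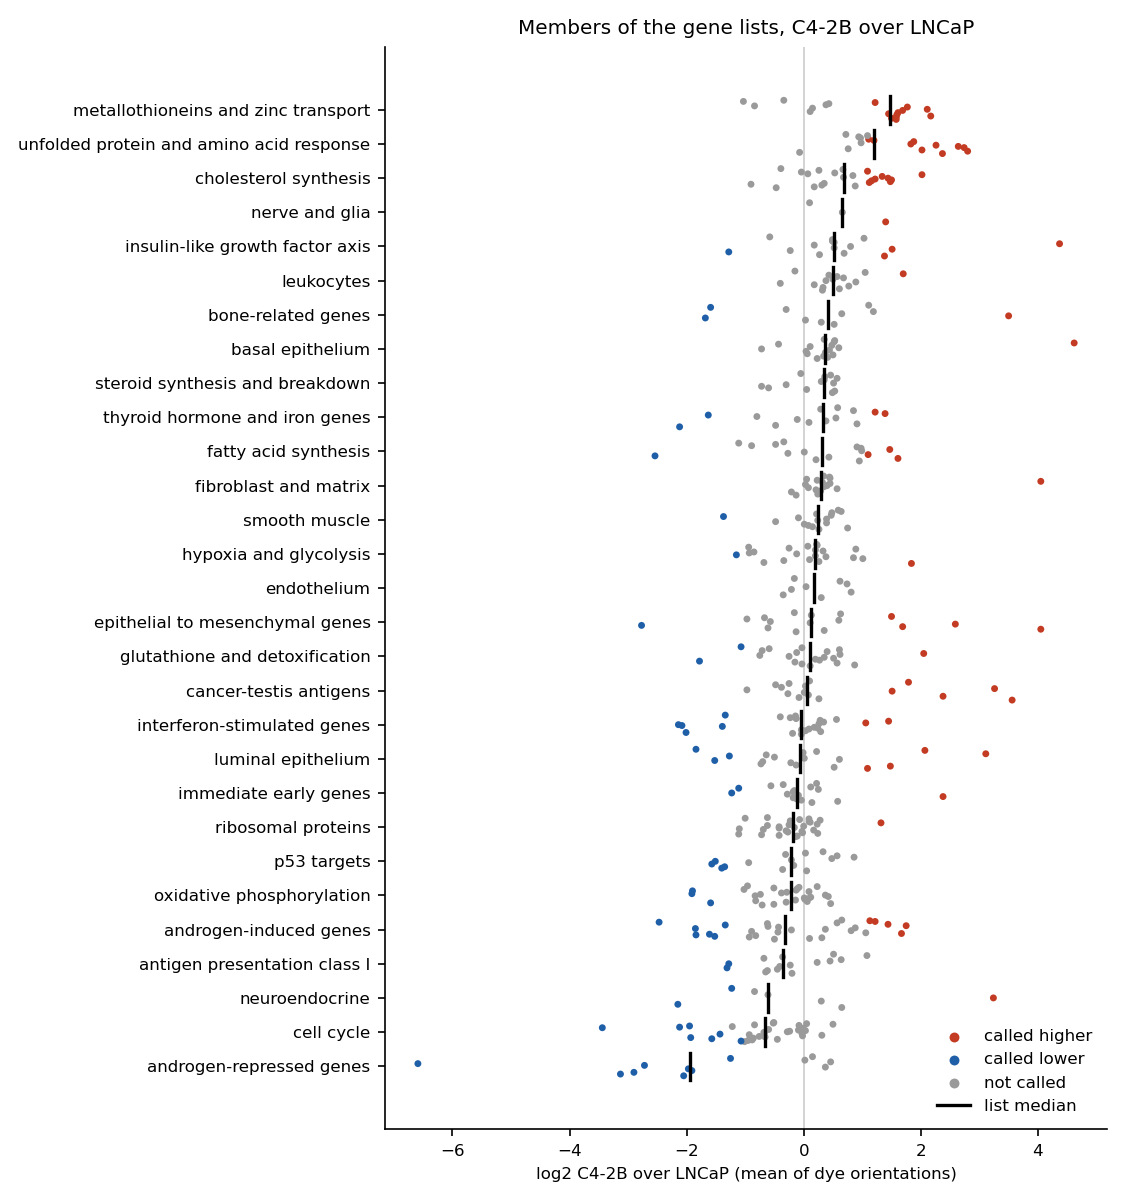
Log2 ratio of C4-2B over LNCaP (horizontal axis) for each measured member of the 29 gene lists (vertical axis), with genes called higher in red, called lower in blue, others in grey and the list median as a black bar. The metallothionein median lies at 1.47 and that of the androgen-repressed genes at -1.94.

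The comparison of LNCaP with the benign prostate pool set the parent line against RNA of whole benign tissue. Markers of smooth muscle, fibroblasts, endothelium and leukocytes were mostly lower in both lines, so ratios to the pool do not compare like cells. A lower call against the pool cannot be told apart from a difference in cell types. Most cell cycle genes were higher in LNCaP than in the pool, and most basal, smooth muscle, and fibroblast and matrix markers were lower. CENPF was 6.97 ± 0.08 higher on the log2 scale, and the mitotic kinase gene PBK 6.36 ± 0.01. The hemoglobin gene HBB read -9.46 ± 0.41, and the secretory genes MSMB and ACP3, which encode microseminoprotein and prostatic acid phosphatase, read -8.63 ± 0.12 and -8.19 ± 0.08. Of 14549 genes compared, 1886 were higher in LNCaP and 3265 were lower, against 0 and 0 with the sign of 1 orientation turned. The median of all genes was -0.12, and centring on the median in place of loess moved it to 0.33.

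The other leading higher genes were NMU (6.34 ± 0.24), PCLAF (5.78 ± 0.01), UBE2T (5.56 ± 0.21), CDK1 (5.54 ± 0.03), BIRC5 (5.53 ± 0.22), OIP5 (5.51 ± 0.21), UBE2C (5.49 ± 0.19) and RPL22L1 (5.44 ± 0.70). Below background in the pool were ASPM (at least 28.5-fold higher in LNCaP), ESCO2 (at least 19.7-fold) and CENPA (at least 15.9-fold). Lower in LNCaP were also NPY (-8.82 ± 0.30), A2M (-8.65 ± 0.15), RGS2 (-8.11 ± 0.33), VIM (-8.05 ± 0.01) and the semenogelin gene SEMG1 (-8.02 ± 0.08). FBLN1 and IGFBP7 each read -7.91. OLFM4 was at least 616-fold lower, the basal cell factor gene TP63 at least 177-fold and ELAPOR1 at least 97.3-fold.

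Cell cycle genes had 31 of 34 members higher in LNCaP, 0 lower and 3 not called. Here and below, members of a list with no call given were not called. Cancer-testis antigens had 10 of 13 higher, 1 lower (PAGE4, -5.07 ± 0.60) and 2 not called. PRAME was higher at 5.01 ± 0.33, MAGEA6 at 4.54 ± 0.27 and MAGEA10 at 4.21 ± 0.20. Androgen-repressed genes had 7 of 11 higher, 2 lower and 2 not called, with UGT2B15 at 4.83 ± 0.38, BCHE at 4.78 ± 0.06 and the chemokine receptor gene CXCR4 lower at -4.27 ± 0.02. Oxidative phosphorylation genes had 9 of 28 higher, led by COX5A (1.70 ± 0.12), and 0 lower. Fatty acid synthesis genes had 6 of 16 higher, led by ME1 (2.42 ± 0.11) and ELOVL6 (2.21 ± 0.12), and 0 lower. FOLH1 was higher at 1.63 ± 0.01.

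Every measured smooth muscle and fibroblast and matrix marker, 19 and 22 genes, was lower in LNCaP than in the pool. Smooth muscle examples were SYNPO2 (-8.72 ± 0.23) and the calponin gene CNN1 (-6.92 ± 0.19), and the decorin gene DCN read -7.67 ± 0.14. Basal markers had 17 of 18 lower, with DKK3 at -7.87 ± 0.38 GSTP1 at -7.81 ± 0.15 and KRT5 at -4.11 ± 0.02. Endothelial markers had 13 of 14 lower (CLDN5, -5.26 ± 0.15), leukocyte markers 15 of 19 (HLA-DPA1, -5.12 ± 0.17), nerve and glia markers 5 of 7 (PMP22, -6.38 ± 0.27) and none of these 3 lists had a higher gene. Neuroendocrine markers had 6 of 15 lower (UCHL1, -3.82 ± 0.09) and 1 higher, SYT4 (4.20 ± 0.31). Luminal markers had 10 of 18 lower and 1 higher. The keratin gene KRT19 read -5.55 ± 0.09, KRT8 was lower at -1.39 ± 0.24 with a further probe at 0.22, and KRT18 read -0.65 ± 0.12.

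Androgen-induced genes had 11 of 28 lower in LNCaP than in the pool, 4 higher and 13 not called, with a median of -0.81 that became 0.04 under median centring. NDRG1 was lower at -4.01 ± 0.01, MAF at -3.99 ± 0.01, TRPM8 at -3.66 ± 0.05, KLK2 at -3.57 ± 0.34, KLK3 at -2.86 ± 0.13 and TMPRSS2 at -1.53 ± 0.27. The other KLK3 probes read -1.13 and -0.53. Metallothionein and zinc transport genes had 13 of 18 lower, led by MT1M (-6.23 ± 0.05) and MT1E (-4.70 ± 0.20), and 1 higher. Immediate early genes had 15 of 20 lower (EGR1, -5.82 ± 0.06, and FOS, -5.79 ± 0.07) and 1 higher. Interferon-stimulated genes had 15 of 25 lower (IFI27, -4.12 ± 0.04) and class I antigen presentation genes 11 of 15 (PSMB8, -4.36 ± 0.15, and B2M, -3.45 ± 0.00), with 0 higher in either. The insulin-like growth factor axis had 12 of 15 lower (IGFBP5, -6.27 ± 0.06) and 0 higher, and bone-related genes had 11 of 15 lower (SPARC, -6.13 ± 0.14, and SPP1, -3.21 ± 0.04) and 1 higher. Glutathione and detoxification genes had 12 of 22 lower (GPX3, -4.90 ± 0.25) and 4 higher, and epithelial to mesenchymal genes 10 of 20 lower (S100A4, -4.75 ± 0.13) and 1 higher.

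Steroid synthesis and breakdown genes had 5 of 14 lower, among them the 5-alpha reductase gene SRD5A2 (-5.54 ± 0.33), and 1 higher. Cholesterol synthesis genes had 5 of 23 lower (SC5D, -2.10 ± 0.03) and 0 higher. Thyroid hormone and iron genes had 5 of 14 lower (the iron exporter gene SLC40A1, -4.96 ± 0.01) and 3 higher (TFRC, 2.67 ± 0.15). The unfolded protein and amino acid response had 4 of 17 lower (XBP1, -2.68 ± 0.09) and 3 higher (PSAT1, 1.99 ± 0.16), hypoxia and glycolysis 3 of 21 lower (VEGFA, -4.33 ± 0.03) and 3 higher, and p53 targets 2 of 15 lower (BTG2, -2.02 ± 0.20) and 1 higher (FDXR, 1.66 ± 0.09). None of 30 ribosomal protein genes was called. Further probes that were not called read -0.24 for FBLN1, -0.42 for TP63, -0.83 for MT1E and 0.16 for KRT18. Further probes with the same call but a smaller ratio read 2.60 for CENPF, 2.76 for ASPM, -4.28 for OLFM4, -5.27 for ACP3, -4.10 for FBLN1, -3.68 for SYNPO2, -4.78 and -5.53 for DKK3, -4.24 and -1.58 for IGFBP5 and -2.39 and -3.07 for VEGFA. PAGE4, SYNPO2 and SPP1 were above background on 1 of 2 LNCaP arrays, and PRAME, MAGEA10, UGT2B15 and SYT4 in the pool on 1 of 2, so their ratios rest partly on dim signal.

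The comparison of C4-2B with the same pool asked how far the derivative lies from whole benign tissue, with the same limit on cell types. Most cell cycle genes and cancer-testis antigens were again higher, and most basal, smooth muscle, and fibroblast and matrix markers lower. UBE2C, a ubiquitin-conjugating enzyme gene of mitosis, was higher at 5.21 ± 0.05 and the antigen gene PRAME at 5.11 ± 0.13. HBB read -8.95 ± 0.38, MSMB -8.62 ± 0.96 and NPY -8.21 ± 0.26. Of 14713 genes compared, 1808 were higher in C4-2B and 3528 were lower, against 0 and 0 with the sign of 1 orientation turned. The median of all genes was -0.16, and median centring moved it to 0.18.

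BIRC5 (4.93 ± 0.09), RPL22L1 (4.92 ± 0.46), PIMREG (4.87 ± 0.07), PAGE1 (4.87 ± 0.16), the thymidine kinase gene TK1 (4.77 ± 0.20), OIP5 (4.68 ± 0.12), MOCOS (4.54 ± 0.09) and GAGE12F (4.51 ± 0.13) completed the 10 highest measured genes. MAGEA1 was at least 70.8-fold higher, TYMSOS at least 15.1-fold and CENPA at least 14.5-fold. A2M (-8.21 ± 0.27), GSTP1 (-7.71 ± 0.30), FHL2 (-7.65 ± 0.19), DCN (-7.59 ± 0.33), ACP3 (-7.58 ± 0.49), FBLN1 (-7.56 ± 0.40) and S100A6 (-7.54 ± 0.36) were among the lowest. SPARCL1 was at least 153-fold lower, ANXA1 at least 111-fold and TP63 at least 102-fold.

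Cell cycle genes had 29 of 35 members higher in C4-2B than in the pool and 1 lower, with CCNB1 at 4.03 ± 0.17, and cancer-testis antigens had 12 of 15 higher and 1 lower (PAGE4, -5.46 ± 0.23). The unfolded protein and amino acid response had 10 of 18 higher, led by ASNS (4.37 ± 0.23), TRIB3 (3.99 ± 0.20) and HSPA5 (2.34 ± 0.09), and 2 lower. A further ASNS probe read 0.12 and a further HSPA5 probe -0.33, neither called. Androgen-repressed genes had 4 of 11 higher (DDC, 4.09 ± 0.03) and 4 lower (CXCR4, -5.53 ± 0.03, and MET, -2.10 ± 0.06). Fatty acid synthesis genes had 5 of 16 higher (ME1, 3.41 ± 0.10) and 1 lower, MCAT, whose probes went opposite ways at -1.38 and 1.49. Cholesterol synthesis genes had 5 of 23 higher (NSDHL, 1.44 ± 0.13, and INSIG1, 1.42 ± 0.02) and 1 lower. Oxidative phosphorylation genes had 6 of 28 higher (ATP5F1C, 1.54 ± 0.07) and 2 lower, and hypoxia and glycolysis genes 5 of 21 higher (ENO1, 1.41 ± 0.13) and 3 lower (ADM, -4.96 ± 0.11). Ribosomal protein genes had 1 of 34 higher and 4 lower, among them RPS20 (-1.42 ± 0.40), RPLP1 (-1.40 ± 0.24) and RPL11 (-1.18 ± 0.01), which read 0.31, 0.39 and 0.49 under median centring.

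Smooth muscle markers had 20 of 20 lower in C4-2B than in the pool (the desmin gene DES, -6.86 ± 0.44), fibroblast and matrix markers 22 of 22 (COL1A2, -5.98 ± 0.10) and basal markers 16 of 18 (KRT15, -6.02 ± 0.23, and KRT5, -3.88 ± 0.19). Endothelial markers had 11 of 14 lower (VWF, -4.88 ± 0.15), leukocyte markers 14 of 19 lower (HLA-DRA, -4.44 ± 0.19) and 1 higher, and nerve and glia markers 4 of 8 lower (S100B, at least 5.81-fold). Neuroendocrine markers had 6 of 16 lower (CPE, -4.74 ± 0.03) and 2 higher (SYT4, 3.36 ± 0.11). Luminal markers had 9 of 18 lower (CD24, -6.14 ± 0.18) and 0 higher, and KRT8 and KRT18 read -0.30 ± 0.22 and -0.13 ± 0.17, with a further KRT8 probe at 1.25. Androgen-induced genes had 14 of 29 lower and 3 higher. SLC45A3 was lower at -4.69 ± 0.05, MAF at -4.21 ± 0.15, KLK2 at -3.47 ± 0.05, KLK3 at -3.36 ± 0.13 and TMPRSS2 at -2.46 ± 0.13, while FOLH1 read 0.36 ± 0.08, with a further probe higher at 1.25. The other KLK3 probes read -2.34 and 0.42.

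Immediate early genes had 16 of 20 lower in C4-2B than in the pool (EGR1, -6.00 ± 0.07) and 2 higher, interferon-stimulated genes 17 of 25 lower (MX1, -3.76 ± 0.15) and class I antigen presentation genes 11 of 15 lower (HLA-F, -4.41 ± 0.08). Metallothionein and zinc transport genes had 12 of 18 lower (MT1M, -6.11 ± 0.08) and 3 higher, the insulin-like growth factor axis 11 of 16 lower (IGFBP7, -7.41 ± 0.26) and 1 higher, and bone-related genes 10 of 18 lower (CTSK, -4.23 ± 0.01, and SPP1, at least 7.31-fold) and 1 higher. Glutathione and detoxification genes had 12 of 22 lower (ALDH1A1, -3.99 ± 0.16) and 5 higher, and epithelial to mesenchymal genes 9 of 21 lower (CDH3, -3.87 ± 0.12) and 3 higher. Steroid synthesis and breakdown genes had 4 of 14 lower (HSD17B6, -4.17 ± 0.00) and 2 higher, thyroid hormone and iron genes 6 of 14 lower (DIO2, -2.96 ± 0.01) and 3 higher, and p53 targets 4 of 16 lower (BTG2, -3.42 ± 0.23) and 2 higher. Further probes that were not called read -0.41 for TP63, -0.12 for MET, 1.03 for ME1, -1.03 for COL1A2, -0.41 for VWF, -0.65 for DIO2 and 0.25, 0.06 and 0.47 for KRT18. Further probes with the same call but a smaller ratio read 3.58 for PRAME, -4.74 for ACP3 and -3.43 for FBLN1. ALDH1A1 was above background on 1 of 2 C4-2B arrays.

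Genes that differed from the pool in both lines included BIRC5, UBE2C, OIP5, PRAME and RPL22L1 among the higher and HBB, MSMB, NPY, A2M, ACP3 and TP63 among the lower. Of 14256 genes compared in both, 951 were higher in both lines and 2543 lower in both. Independent lists of the same sizes would share 228.3 and 801.6. Simulated lines without change, drawn from the array noise alone, shared 0 and 0. The simulation leaves out real effects, and both the simulation and the independent lists leave out the shared pool. The simulated noise had an SD of at most 0.255 in either line, far below the log2 threshold of 1. Noise alone could therefore hardly give shared calls, and the simulated counts say little about the excess. Part of the excess may come from the pool RNA, which neither comparison can show.

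**Figure D3:**
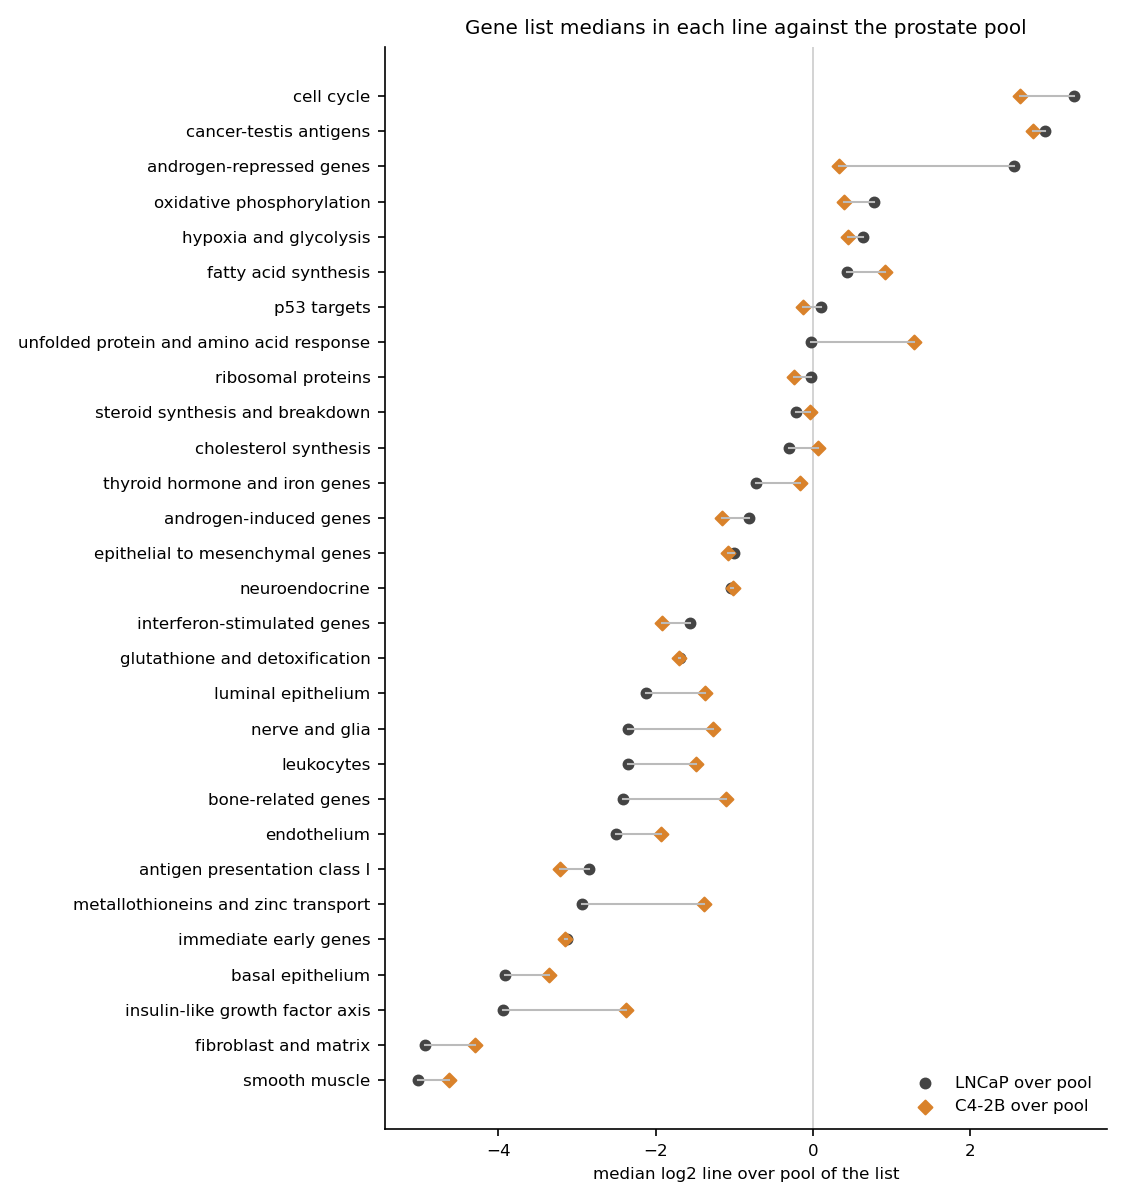
Median log2 ratio of line over prostate pool (horizontal axis) of the 29 gene lists (vertical axis), with LNCaP as circles and C4-2B as diamonds. The cell cycle medians lie at 3.32 and 2.63, and the smooth muscle medians at -5.02 and -4.62.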

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

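The tests in this part were chosen only after the calls between the lines had been seen.

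The lines lay on opposite sides of the pool for 44 genes, and this difference between lines was not tested. Higher in LNCaP and lower in C4-2B were 29 genes, among them BCHE (4.78 and -1.81), PHIP (1.56 and -2.35), ATP1B1 (1.71 and -1.85) and 7 zinc finger genes, such as ZNF254 (1.84 and -1.58). Lower in LNCaP and higher in C4-2B were 15 genes, among them ASCL2 (-3.89 and 1.23), SLC7A5 (-1.47 and 2.66), FN1 (-1.07 and 1.52) and ATF3 (-1.31 and 1.07). These values are those of the brightest probes. In LNCaP over pool, further probes of FN1 (-0.78 and -0.13), ATF3 (-0.53) and ATP1B1 (0.97) had the same sign but were not called. In C4-2B over pool they had the same call. The other ASCL2 probe, too dim to be compared, read -0.07 and 0.03.

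Probes without a gene name, which the comparisons did not use, also differed between the lines. Of 7544 compared, 333 were higher in C4-2B and 716 lower, against 1 call with the sign of 1 orientation turned.

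Each line had a scan day of its own, and the pool channel, which should not differ between days, gave a control for the genes called between C4-2B and LNCaP. By the same rule 36 of 13480 genes were called between the pool channels, 29 higher and 7 lower on the C4-2B arrays, against 918 and 1620 called between the lines. An effect of equal size in both channels of an array cancels in the ratios and could give no calls. One of unequal size that reached both channels would have moved the pool too. The genes called higher and lower had median pool shifts of 0.06 and -0.08, against median line-channel shifts of 1.53 and -1.60. These values argue against an array batch of unequal size in both channels as the cause of most calls. Of the 36 genes, 13 were called the same way between the lines and 1 the opposite way, so a batch of unequal size in both channels stays open for those 13. A difference in the line RNAs themselves before hybridisation would not show in the pool, and the growth medium cannot be told apart from the line because each line had 1 medium. A biological difference between the lines stays open and untested.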

How the results depend on the processing

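The removal of the length trend and of pool-dominated genes was chosen after the data had been seen, and all other alternatives before. Of 150 alternative counts, 128 stayed within 1.5 times the reported count. Not all of these are separate checks. The series table counts nearly repeat the Feature Extraction ones, and counts of a line against the pool with 1 of its arrays left out repeat those of 1 orientation alone. The genes higher in C4-2B than in LNCaP numbered 918, against 2327 at 1.5-fold, 288 at 3-fold, 1447 by Feature Extraction log ratios and 1440 by series table values. The genes lower in C4-2B than in LNCaP numbered 2957 at 1.5-fold and 609 at 3-fold. For LNCaP over pool, higher calls numbered 3164 at 1.5-fold, 864 at 3-fold and 3095 by both deposited ratios, and lower calls 2076 at 3-fold. For C4-2B over pool, higher calls numbered 3253 at 1.5-fold, 731 at 3-fold, 3256 (Feature Extraction) and 3257 (series table), and lower calls 2335 at 3-fold. Higher in both lines were 1870 at 1.5-fold, 370 at 3-fold and 1877 by either deposited ratio, and lower in both 1633 at 3-fold. These ratios were not shrunk by an offset, and the cause of their higher counts was not tested. With arrays left out, counts ranged from 935 to 1489 (higher) and 1783 to 1992 (lower) for C4-2B over LNCaP. They required only the mean ratio to reach 2-fold, a rule that gave 1100 and 1846 with all arrays. Leaving out 1 array also left the dyes unbalanced between the lines. The share of higher calls rose under median centring from 36.6% to 47.6% (LNCaP over pool) and from 33.9% to 46.1% (C4-2B), and in both lines from 27.2% to 37.1%. By deposited ratios it was 44.1% for C4-2B and 39.1% in both lines. Removal of the length trend left 893 higher and 1578 lower, and leaving out pool-dominated genes 909 and 1614. Leaving out saturated probes or the filter on dim probes changed no count.

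The cutoff for a move was the same for all values of a comparison and exceeded the error of most genes. It was 0.29 for C4-2B over LNCaP, 0.365 for LNCaP over pool and 0.279 for C4-2B over pool. Of 744 alternative values of 51 list medians that stood apart, 159 moved by more than this cutoff. Only 1 changed sign: androgen-induced genes in LNCaP over pool, at 0.04 under median centring. Of 4497 alternative values of 370 called named genes, 1035 moved by more than the cutoff of their comparison, and 6 changed sign. Sign changes were seen for PAGE1 between the lines (-0.12 by both deposited ratios), and in C4-2B over pool for MCAT (0.05 by the mean of its probes), RPS20 (0.31), RPLP1 (0.39) and RPL11 (0.49), the last 3 under median centring. The causes were not tested. No paired analysis was possible because each line was 1 sample and no test was made. Genes below background on both arrays of 1 RNA have no exact fold, and their values depended on the route used.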

Other observations

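All tests in this part were chosen after the data had been seen.

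Genes lower in C4-2B than in LNCaP lay next to each other on chromosomes. In a run of 25 neighbouring genes on chromosome 19 from ATP13A1 to ZNF254, nearly all zinc finger genes, 16 were lower and 0 higher, with a median of -1.53. Sharing of signal between the zinc finger probes was not tested. On chromosome 4, the run from CLOCK to UGT2B28 had 14 lower and 1 higher, with the purine synthesis genes PAICS (-1.92) and PPAT (-1.59), NMU (-2.69) and the UGT2B cluster lower, and the homeobox gene HOPX higher at 3.31. On chromosome 7, the run from STEAP1 to PPP1R9A had 16 lower and 1 higher, with STEAP1 (-1.70), STEAP2 (-1.61), AKAP9 (-3.40), SGCE (-1.96) and PPP1R9A (-2.41) lower. The highest run, on chromosome 11 from TSPAN18 to ACP2, had 6 higher and 0 lower with a median of 0.82, and the growth factor gene MDK read 2.09. By chromosome the medians ran from -0.60 on chromosome 4 to 0.33 on chromosome 22.

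Gene families grouped by symbol after the data were seen held varying numbers of called genes, and no family was tested. Of all genes compared, 12.02% were called lower in C4-2B and 6.81% higher. Of 37 genes named CEP, most of them centrosomal, 18 were lower and 0 higher. Of 393 ZNF genes, 93 were lower and 11 higher, and of 31 kinesin genes (KIF), 11 were lower and 1 higher. Nucleoporin genes (NUP) had 6 of 22 lower and 0 higher. Solute carrier genes (SLC) had 32 of 262 higher and 22 lower. Against the pool, 14 of 26 MRPS and 20 of 49 MRPL genes, which encode mitochondrial ribosomal proteins, were called higher in LNCaP and 0 lower, where 12.96% of all genes were called higher. In C4-2B 8 of 28 MRPS and 10 of 50 MRPL genes were called higher and 0 lower, where 12.29% of all genes were called higher.

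The shift of neighbouring genes between the lines correlated at 0.20 across 13382 pairs, against at most 0.02 in 200 shuffled gene orders. For LNCaP over pool and for C4-2B over pool it was 0.11 each, so a correlation between neighbours is not particular to the comparison of the lines. In the pool channel the correlation was 0.04, which argues against an array batch of unequal size in both channels as the whole cause. A batch of equal size in both channels cancels in the ratios. Between the lines the correlation was 0.18 after removal of the trend with gene length and 0.18 without neighbours that share a symbol root. These values argue against length, or signal shared within families, as the whole cause of the correlation across genes. The test without shared roots does not reach the zinc finger run on chromosome 19, where shared signal stays open. A copy number difference between the lines stays open, since no DNA was measured. Of genes in the 19 lowered runs 83.6% were below 0, but the runs were chosen for their low medians, so this share speaks for no explanation. Their cutoff came from shuffled orders scanned at fewer windows than the data, which made it easier to reach. Base composition, with 0 reference columns that give it, and the quality of the line RNA stay open too.

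Of the 17 measured unfolded protein and amino acid response genes, 10 were called higher in C4-2B. All 17 together had a median pool shift of 0.15 against a median line-channel shift of 1.91 and a median ratio of 1.20. These values argue against an array batch of unequal size in both channels, and one of equal size cancels in the ratios. The median ratio of the 17 genes was 1.34 after removal of the trend with gene length, which argues against length bias. A response to T-medium could give the same values, and with 1 medium per line it cannot be told apart from a difference between the lines, which was not tested.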
